A study of Homo sapiens with 9 samples.

How the data were processed

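Gene expression was measured on Affymetrix arrays in 9 samples of K562, an established human leukaemia line with erythroid and megakaryocytic potential. Per the labels, the cells were transduced with retroviral supernatant in 4 cycles, 1 every 12 h, and kept in culture for a further 36 h. Cells carrying the NGFR surface marker were selected with magnetic beads, and their purity 48 h after selection was above 90%. Total RNA came from 100000 cells per sample. There were 3 groups of 3 arrays: the wild-type form of calreticulin (CALR), the Del52 form and the Ins5 form.

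The deposited values are log2 expression values per probe set, 1 column per array. Per the submitters' processing notes, the tools were Partek and RMA, which corrects background, normalizes between arrays and summarises the probes of a probe set. Versions and settings are not given in the sources used here. The base of the logarithm was read from the values: the highest value, 12.2, would exceed the range of the scanner if it were a natural logarithm. Array medians lay between 3.73 and 3.76. Arrays give no read depth, so the number of arrays limits the precision. Signal over background could not be set by 1 floor, because the 23 antigenomic control probe sets spanned 1.53 to 6.52.

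The table held 49386 probe sets, of which 93 were controls and were left out of all tests. In the platform annotation used here, 45259 probe sets had 1 gene symbol, 1327 had several and 2713 had none. Only the first kind was used. Of these, 45178 matched the RefSeq gene table of GRCh38.p14 by gene identifier, and 0 symbols needed an update. No build is named for the array's own annotation, so no coordinates are given. Of the genes, 11823 had more than 1 probe set. The probe set with the highest mean over all 9 arrays stood for its gene, which left 18239 genes.

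Genes were tested with limma 3.58.1 in R 4.3.3. All 9 arrays entered 1 fit with a mean per group and moderated variances, with 6 residual degrees of freedom. The contrasts were Del52 against wild type, Ins5 against wild type, Del52 against Ins5, and the mean of both mutants against wild type. A moderated F test covered all 3 groups. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes, with no fold threshold. All p-values are two-sided.

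A total of 24 gene lists were fixed from general knowledge before the data were examined, as were the tests, the alternatives and the rule for naming genes. The lists held 975 entries, of which 910 were measured, and the remaining entries were not analysed here. They covered ER chaperones and folding enzymes of the unfolded protein response, ER-associated degradation, the PERK-ATF4 integrated stress response, NRF2 targets, antioxidant enzymes, proteasome subunits, DNA repair, cell cycle, apoptosis regulators, JAK-STAT targets and feedback, MAPK output, erythroid genes, and megakaryocyte and platelet genes. Markers of other cells (granulocytes and monocytes, lymphoid cells, fibroblasts and epithelia) were included. The remaining lists were interferon response, antigen processing and MHC class I, cholesterol biosynthesis, glycolysis and hypoxia, oxidative phosphorylation, ribosome biogenesis and MYC targets, calcium handling of the ER, and cytosolic heat shock. Each list was tested against all other genes with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, a rotation test of each list on its own, were alternatives.

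Named genes were CALR and NGFR, up to 10 rises and 10 falls past the threshold with groups that did not overlap, up to 4 passing members per list or otherwise the member with the smallest p, and, where fewer than 5 genes passed, the 5 with the smallest unadjusted p. Further list members are named by their place at the head of a list or because they passed when adjusted over the list alone, and that choice was made after their values were seen.

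No block entered the main design, and the replicate number as a block was an alternative. Other alternatives were quantile normalization, median centring, genes above the median level, the mean of all probe sets, single probe sets, an intensity trend, array weights, unmoderated variances, 6 arrays per comparison, other thresholds and each array left out. After the data were seen, the first principal component of the 9 arrays was added as a covariate, and both arrays at its ends were left out together, which assumes that the 1 wild-type array left varies like the other groups. Correlations over the 9 arrays were tested with exact permutation tests over 362880 pairings (Python 3.11.15, numpy 2.4.6). After the data were seen, the slope of each list on the main axis was compared with 1000 random gene sets of the same size and expression level.

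The gene test was tested on simulated data, arrays with the real gene means, spread and main axis, for Del52 against wild type over 18239 genes. It recovered 50.7% of 67 genes changed by 0.5 on the log2 scale, 73.1% of 67 changed by 1 and 97.0% of 66 changed by 2, with 0 unchanged genes called. With the first principal component as covariate the shares were 82.1%, 98.5% and 100%, with 7 unchanged genes called. In a simulation without the main axis and with the proteasome list shifted by 0.3 in Del52, that list alone was called. The simulated genes varied independently, and the shift was larger than the median of 0.09 observed for that list. It therefore does not show how the list test behaves with genes that vary together. Nothing in the labels says that replicates were separate cultures, so the p-values measure the spread between these samples, which can be technical.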

Results

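Expression of 18239 genes was measured in K562 cells carrying 1 of 3 forms of calreticulin, an ER chaperone that binds glycoproteins and calcium. The wild-type form, the Del52 deletion and the Ins5 insertion were each represented by 3 arrays. Both mutations change the end of the protein and are known from myeloproliferative neoplasms. By its title the study asked how the mutants affect the unfolded protein response and the response to oxidative stress. Values are authors' RMA values on the log2 scale, and all gene tests are limma contrasts with Benjamini-Hochberg adjustment.

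The transduced gene and the selection marker were examined first. The CALR probe set with the highest signal read 7.42 ± 0.18 in Del52, 7.40 ± 0.12 in Ins5 and 7.57 ± 0.24 in wild type (SD, n = 3 each). Neither mutant passed the limma test against wild type (log2 fold change -0.15, adjusted p = 0.918 for Del52 and -0.16, adjusted p = 0.893 for Ins5). A second, dimmer CALR probe set read 4.37 in Del52, 4.28 in Ins5 and 3.86 in wild type. Its log2 fold changes were 0.51 ± 0.11 (SE) for Del52 and 0.42 ± 0.11 for Ins5, with adjusted p = 0.602 and 0.522 over all probe sets. The unadjusted limma p was 0.0015 and 0.0048. Every mutant array (4.17 to 4.47) lay above every wild-type array (3.68 to 4.01), all within the span of the antigenomic controls. NGFR, the surface receptor used for selection, read 3.42, 3.43 and 3.36, within the span of the antigenomic controls. The position of these probes relative to the transduced sequences is not known here, so the levels neither bear out nor contradict the labels.

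The arrays differed more within groups than between them. The first principal component held 70.5% of the variance over all genes, and the second held 10.0%. Differences between groups held 13.4%, against 25% expected by chance alone. The wild-type arrays of replicates 2 and 3 lay at opposite ends of the first component, with scores of 0.57 and -0.57, and correlated at 0.975, the lowest of any pair. The highest correlation between arrays, 0.998, joined different groups.

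**Figure D1:**
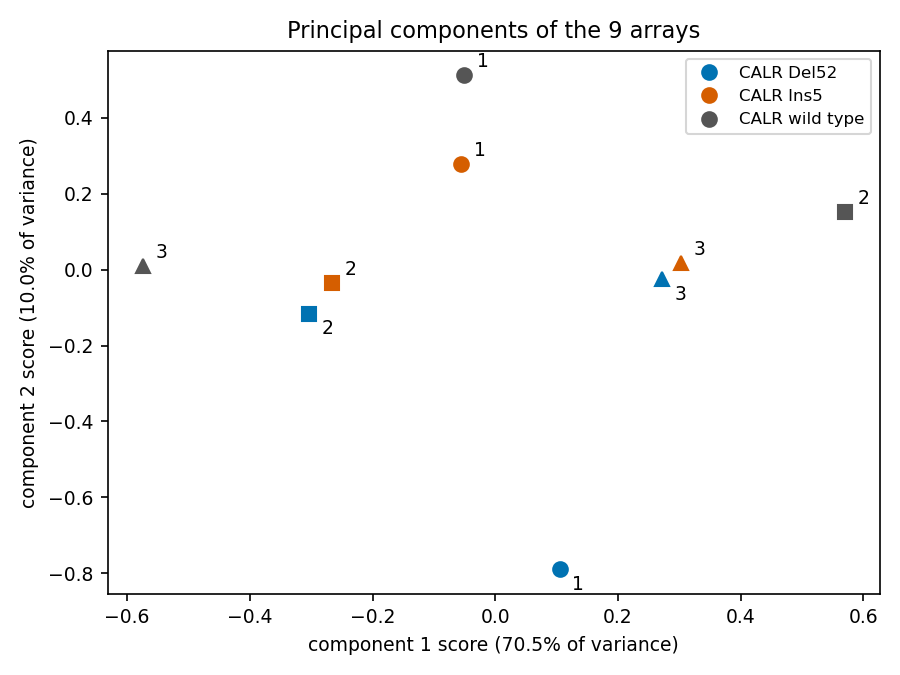
Scores of the 9 arrays on the first (x axis) and second (y axis) principal component of 18239 genes. Points are arrays, coloured by CALR form, and shapes and digits give the replicate number. Wild-type replicates 2 and 3 lie at 0.57 and -0.57 on the first component, and Del52 replicate 1 lies at -0.79 on the second.

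The effect of the deletion mutant was read from Del52 against wild type. Genes of the PERK-ATF4 integrated stress response, the arm that adjusts translation and amino acid supply, were lower in Del52: 39 of 41 measured members had negative log2 fold changes, with a median of -0.23. The list fell in the camera test (adjusted p = 3.0e-07), but adjusted p = 0.809 with an estimated correlation. EIF2AK3, which encodes the kinase PERK, had the smallest p of the list (log2 fold change -0.35 ± 0.07 SE, limma adjusted p = 0.603, lower in every Del52 array than in every wild-type array). The transcription factors ATF4 and DDIT3 had values of -0.20 and -0.35, and ASNS, which makes asparagine, had -0.25. None of these members passed. Del52 arrays differed widely in the list, at -0.60, 0.15 and -0.20 around the mean of all arrays, and 2 of 3 lay below the wild-type mean. Without Del52 replicate 1 the median was -0.06 (camera adjusted p = 0.0384). Del52 replicate 1 also stood apart in other respects, with a score of -0.79 on the second component, the highest labelling spike of the 9 arrays (6.59), the highest hybridisation spike (6.18) and the second-lowest actin 3-prime minus 5-prime difference (1.18). The hybridisation spike was higher in every Del52 array (6.18, 6.15 and 6.07) than in any other array (at most 6.04), so this control differed with the group. It was picked out after the controls were seen, without a test. The labelling spike did not separate Del52 (6.32 in Del52 replicate 2, 6.50 in wild-type replicate 3). The 18S control was higher in every Del52 array (at least 10.06) than in every Ins5 array (at most 9.72), but not than in every wild-type array. The list median was -0.13 without wild-type replicate 3, -0.43 without wild-type replicate 2 and -0.42 without Del52 replicate 2.

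Subunits of the proteasome, the protease complex that degrades ubiquitinated proteins, were slightly higher in Del52. Of 37 measured subunits, 36 had positive values, with a median of 0.09 (camera adjusted p = 0.00106), and all 3 Del52 arrays lay above the wild-type mean. The adjusted p was 0.708 with an estimated correlation, and the median was 0.056 without wild-type replicate 3. That array was the lowest in the list (-0.108 around the mean of all arrays), and Del52 replicate 2 (-0.020) lay below wild-type replicate 2 (0.016). PSMB4, the subunit with the smallest p, was at 9.41 ± 0.02 in Del52 and 9.28 ± 0.02 in wild type (SD, n = 3 each; limma adjusted p = 0.603).

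ER chaperones and folding enzymes did not move as a list in Del52, with 22 members higher and 22 lower. The median was -0.00, the mean 0.02 and the camera adjusted p = 0.583. Adjusted over the list alone, 6 members passed, while 0 passed over all genes. Of these, 5 were higher: the protein disulfide isomerases PDIA3 (0.42) and PDIA6 (0.22), the chaperone HYOU1 (0.20), the secreted factor MANF (0.53) and TMEM50B (0.45). DNAJB9, a co-chaperone of the ER, was lower (-0.60). The fry test for change in either direction was past the threshold for this list (adjusted p = 0.0135). HSPA5, the major ER chaperone BiP, had a log2 fold change of 0.26 ± 0.10 (SE), and HSP90B1 of 0.19 ± 0.07, both with limma adjusted p = 0.655. ATP2A2, the calcium pump of the ER membrane, was at 9.77 ± 0.01 in Del52 and 9.48 ± 0.07 in wild type (SD, n = 3 each), and passed when adjusted over the calcium list alone (adjusted p = 0.0214), not over all genes (0.603).

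Lists for oxidative stress were not called in Del52. NRF2 targets had 23 of 36 members higher (median 0.04, camera adjusted p = 0.583). NFE2L2, the gene of NRF2 itself, had the smallest p of its list, at 8.80 ± 0.14 against 9.09 ± 0.11 (SD, n = 3 each; limma adjusted p = 0.603). Antioxidant enzymes had 41 of 53 higher (median 0.05, camera adjusted p = 0.209), led by the methionine sulfoxide reductase MSRB1 (0.24, limma adjusted p = 0.606). ER-associated degradation had 16 higher and 16 lower (median 0.01, mean -0.03, camera adjusted p = 0.583), with the lectin ERLEC1 lowest in p (-0.16, limma adjusted p = 0.606).

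Lineage and growth lists were not called either without a covariate. The erythroid list had 35 of 43 members higher (median 0.10, camera adjusted p = 0.197), with the membrane skeleton gene ANK1 at 0.24. The oxidative phosphorylation list had 64 of 72 higher (median 0.04, camera adjusted p = 0.0700), with UQCR11 at 0.12. MAPK output genes had 18 of 24 members lower (median -0.16, camera adjusted p = 0.209). Medians were 0.02 for megakaryocyte and platelet genes (adjusted p = 0.524), 0.04 for the cell cycle (0.543), 0.01 for apoptosis regulators, with a mean of -0.02 (0.887), and -0.01 for the interferon response (0.524). DNA repair had a median of -0.00 (adjusted p = 0.524), glycolysis and hypoxia 0.01 with a mean of -0.00 (0.961), and calcium handling 0.00 with a mean of -0.01 (0.90). Smallest p-values in other lists belonged to H2AX (0.20), GINS1 (0.21), BMF (0.20), ID1 (0.15), EPHA4 (0.12), ALOX12 (0.23), OAS2 (-0.12), HLA-B (0.13), PMVK (0.08), HK2 (0.30), NOP56 (0.26) and DNAJB4 (-0.17), none past the threshold. Markers of other cells were at CTSG 0.17, CD8A 0.23 and COL6A2 -0.30. Their wild-type means were 2.39, 2.99 and 4.61, within the span of the antigenomic controls. As lists, none of the markers of other cells was called (granulocytes and monocytes: 15 of 30 higher, median 0.00, camera adjusted p = 0.885; lymphoid: 13 of 22 higher, median 0.01, adjusted p = 0.885; fibroblasts and epithelia: 16 of 25 higher, median 0.04, mean -0.00, adjusted p = 0.961). The fry test for change in either direction was past the threshold for the fibroblast and epithelial list (adjusted p = 0.00390).

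Over all genes, 0 passed in Del52 against wild type (limma, smallest adjusted p = 0.603). At an unadjusted p under 0.05 there were 1285 genes, where 912 are expected by chance. The 5 smallest unadjusted p-values belonged to COL6A2, EMC1 (0.28), TMEM37 (0.26), DENND10 (-0.29) and AASDH (-0.26). EMC1 encodes a subunit of the ER membrane complex. With the first principal component as covariate, a setting chosen after the data were seen, 4 genes passed: HDC (0.50) and IGFALS (0.33) higher, TIGD2 (-0.46) and FANCF (-0.39) lower. In that setting camera called 7 lists instead of 2, among them the erythroid list (median 0.11, adjusted p = 0.00219), oxidative phosphorylation (0.05, 0.00219), MAPK output (-0.18, 0.00297), cholesterol biosynthesis (0.06, 0.0164) and ribosome biogenesis (0.06, 0.0187). Each of these had an adjusted p = 0.699 with an estimated correlation. None of the 4 genes was called with any 1 array left out. In the simulation the fit with the covariate called 7 unchanged genes. Beside them it called 55 of 67 genes changed by 0.5 on the log2 scale, 66 of 67 changed by 1 and 66 of 66 changed by 2. Those 7 came with many true calls, so their number cannot judge a fit with 4 calls.

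**Figure D2:**
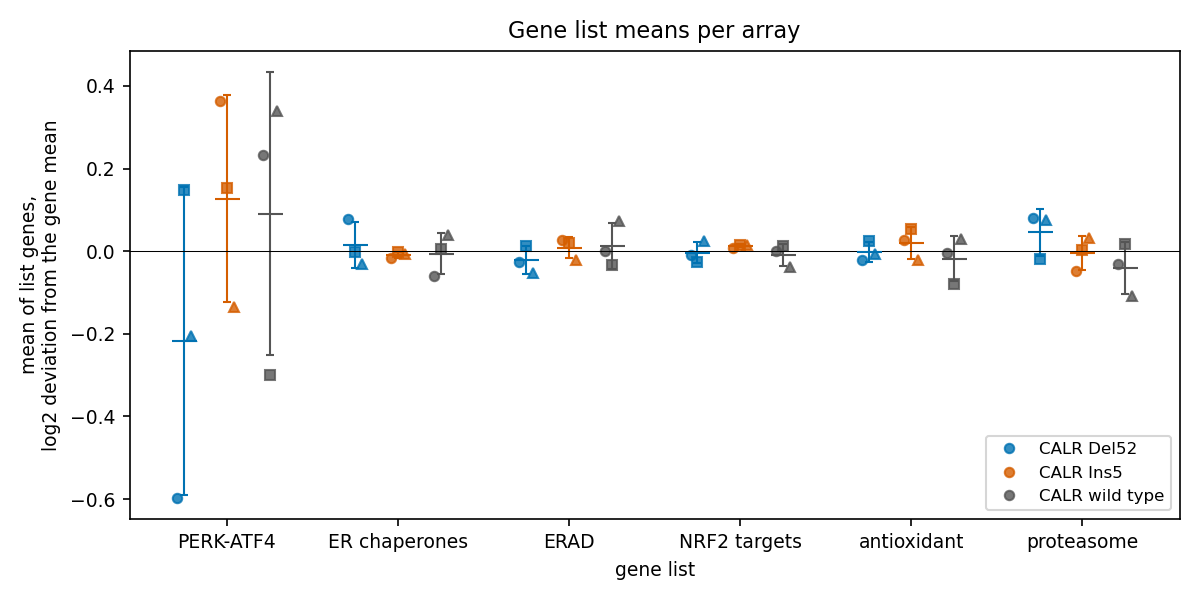
Mean log2 deviation of the genes of 6 lists (x axis) from each gene's mean over all arrays (y axis, log2), per array. Points are arrays (circle, square and triangle for replicates 1, 2 and 3), lines the group mean and bars the SD (n = 3). PERK-ATF4 genes range from -0.60 to 0.36, and Del52 replicate 1 is the lowest.

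The effect of the insertion mutant was read from Ins5 against wild type. No list was called by camera (smallest adjusted p = 0.151). PERK-ATF4 genes had 24 of 41 members higher, with a median of 0.05 and a camera direction that was downward relative to other genes (adjusted p = 0.749). EIF2AK3 was again the member with the smallest p (-0.19 ± 0.07 SE, limma adjusted p = 0.640). ER chaperones had 24 of 44 members higher, with a median of 0.01, a mean of -0.00 and a camera adjusted p = 0.684. Adjusted over that list alone, HYOU1 (0.23) was higher and SSR1, a subunit of the translocon-associated complex, lower (-0.30).

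Other Ins5 values were also small. NRF2 targets had a median of 0.04 (22 of 36 higher, camera adjusted p = 0.972) with the transporter ABCC2 lowest in p (0.22). Antioxidant enzymes had a median of 0.04 (40 of 53 higher, camera adjusted p = 0.554), led by the glutathione peroxidase GPX1 (0.27). ER-associated degradation had a median of 0.02 and a mean of -0.00 (21 of 32 higher, camera adjusted p = 0.646), with NPLOC4 at 0.16. Antigen processing and MHC class I genes had 16 of 20 members higher (median 0.10). Camera did not call this list (adjusted p = 0.151), whereas fry did (adjusted p = 0.00532), as a test of the list alone. MICB, a stress-induced ligand, had the smallest p there (0.16, limma adjusted p = 0.581).

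Adjusted over their lists alone, ATP2A2 (0.26), ID1 (0.21), DNAJB4 (-0.37), CD163 (0.19) and COL6A2 (-0.22) passed in Ins5. Smallest p-values of the remaining lists were at PSMB4 (0.12), FANCB (-0.32), TOP2A (-0.28), AIFM1 (0.10), EPHA4 (0.16), TSPO2 (0.20), PF4V1 (0.15), CD8A (0.23), SAMD9L (-0.13), IDI1 (-0.11), PFKL (0.19), NDUFS8 (0.12) and PA2G4 (0.07). Over all genes, 0 passed (limma, smallest adjusted p = 0.373), with 1351 at an unadjusted p under 0.05 against 912 expected. CACNB1, a calcium channel subunit, had the smallest p (4.45 ± 0.05 in Ins5, 4.07 ± 0.03 in wild type, SD, n = 3 each; limma adjusted p = 0.373), followed by ZNF436 (-0.40), TAF4B (-0.38), TMEM8B (0.24) and OR1L1 (0.22). With the first principal component as covariate 7 genes passed: HDC (0.38), CACNB1 (0.38), DOLK (0.30) and NISCH (0.30) higher, and C1orf74 (-0.36), GOLGA5 (-0.35) and ZNF624 (-0.32) lower. None of these 7 was called with any 1 array left out.

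The mutants were then compared with each other. Camera called 6 lists in Del52 against Ins5. PERK-ATF4 genes fell, with 39 of 41 members lower and a median of -0.33 (adjusted p = 1.4e-06; adjusted p = 0.637 with an estimated correlation), and 2 of 3 Del52 arrays lay below the Ins5 mean. The other 5 lists also had an adjusted p = 0.637 with an estimated correlation. JAK-STAT targets and feedback genes, read out downstream of cytokine receptors, fell with 23 of 29 lower and a median of -0.12 (adjusted p = 0.0375). CISH, a feedback inhibitor of this pathway, was at 7.22 ± 0.11 in Del52 and 7.51 ± 0.15 in Ins5 (SD, n = 3 each; limma adjusted p = 0.841). The list of cytosolic heat shock genes rose (23 of 29 higher, median 0.12, adjusted p = 0.00158), as did ribosome biogenesis and MYC targets (31 of 37, median 0.07, adjusted p = 0.00358), cholesterol biosynthesis (18 of 21, median 0.11, adjusted p = 0.00841) and the proteasome (29 of 37, median 0.05, adjusted p = 0.0164). These medians depended on single arrays. Without Del52 replicate 1, the array with the highest spikes and the score of -0.79 on the second component, they were -0.17 for PERK-ATF4, -0.06 for JAK-STAT, 0.018 for ribosome biogenesis, 0.06 for cholesterol and 0.07 for heat shock, and without Del52 replicate 3 cholesterol had 0.012 and heat shock 0.08. Without Ins5 replicate 1 the medians were -0.22 for PERK-ATF4, 0.04 for ribosome biogenesis, 0.03 for the proteasome and 0.08 for heat shock, and without Ins5 replicate 2 they were 0.03 for ribosome biogenesis, 0.06 for cholesterol and 0.08 for heat shock. Without Del52 replicate 2 they were 0.14 for ribosome biogenesis and 0.18 for cholesterol, and without Ins5 replicate 3 ribosome biogenesis had 0.12. Without Del52 replicate 1, the adjusted p was 0.0825 for the PERK-ATF4 list, 0.397 for JAK-STAT, 0.173 for ribosome biogenesis, 0.0825 for cholesterol and 0.130 for the proteasome. Without Ins5 replicate 1 it was 0.141 for JAK-STAT, 0.0643 for both cholesterol and ribosome biogenesis and 0.250 for the proteasome. It was 0.278 for cholesterol without Del52 replicate 3, and 0.0515 for JAK-STAT without Ins5 replicate 2.

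The ER chaperone list missed the threshold between the mutants (26 of 44 higher in Del52, median 0.03, camera adjusted p = 0.0537), with TMEM50B at 0.20. NRF2 targets had a median of 0.00 and a mean of -0.02 (camera adjusted p = 0.713), with PRDX1 at 0.10. Antioxidant enzymes had a median of -0.01 (adjusted p = 0.714, camera direction upward), with GPX1 at -0.19, and ER-associated degradation -0.00 (adjusted p = 0.882), with UBXN6 at -0.12. In the called lists the smallest p belonged to FGF21 (0.18, opposite to its list), PSMD11 (0.14), PMVK (0.15), NOP56 (0.21) and DNAJB4 (0.20). In other lists it belonged to FANCB (0.25), MCM4 (0.17), MCL1 (-0.15), EPHA2 (-0.09), TRIM58 (0.35), PF4V1 (-0.21), CD163 (-0.15), KLRD1 (0.09), COL6A2 (-0.08), RIGI (-0.12), HLA-F (0.21), HK2 (0.23), NDUFS8 (-0.07) and STIM1 (-0.17). No gene passed: 0 at the threshold (limma, smallest adjusted p = 0.841) and 1052 at an unadjusted p under 0.05, against 912 expected. The smallest p-values were those of PRDM1 (-0.36), GNG7 (0.28), CBX7 (-0.23), SETBP1 (-0.22) and DNAI3 (-0.22).

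**Figure D3:**
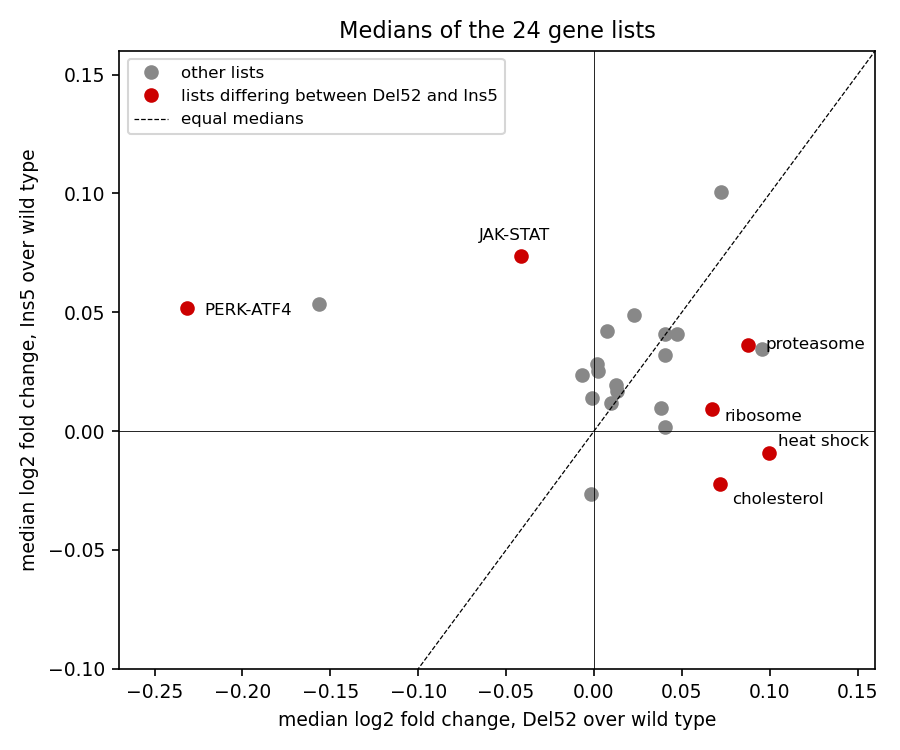
Median log2 fold change of each of the 24 gene lists in Del52 over wild type (x axis) and Ins5 over wild type (y axis). Red points are the 6 lists that differed between the mutants by camera with a preset correlation, and the dashed line marks equal medians. PERK-ATF4 lies at -0.23 for Del52 and 0.05 for Ins5.

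The average of both mutant effects was tested as a contrast of its own. It joins mutants that differed for PERK-ATF4 genes, whose median against wild type was negative in Del52 and positive in Ins5. For PERK-ATF4 genes, 30 of 41 were lower, with a median of -0.09, a camera adjusted p = 0.00457 and an adjusted p = 1.00 with an estimated correlation. The direction did not hold when single arrays were left out, and 3 of 6 mutant arrays lay below the wild-type mean. The median was 0.0064 without Del52 replicate 1 (camera adjusted p = 0.234) and 0.014 without wild-type replicate 3 (0.347). It was -0.038 without wild-type replicate 1 (0.230), -0.012 without Ins5 replicate 3 (0.0936), -0.13 without Del52 replicate 2, -0.14 without Ins5 replicate 1 and -0.28 without wild-type replicate 2. Proteasome genes rose (34 of 37 higher, median 0.07, adjusted p = 0.0380; adjusted p = 0.754 with an estimated correlation), with 5 of 6 mutant arrays above the wild-type mean. By camera, the proteasome adjusted p was 0.137 without Del52 replicate 1, 0.0723 without Del52 replicate 3, 0.119 without Ins5 replicate 2 and 0.0936 without Ins5 replicate 3. It was 0.0844 without wild-type replicate 2 and 0.155 without wild-type replicate 3, where the median was 0.037. Antigen processing and MHC class I genes had 16 of 20 higher (median 0.09, camera adjusted p = 0.0885), and fry called them (adjusted p = 0.0141). Among ER chaperones, 7 members passed when adjusted over the list alone: HYOU1 (0.21), PDIA3 (0.35), PDIA6 (0.21), MANF (0.44) and TMEM50B (0.35) higher, DNAJB9 (-0.52) and SSR1 (-0.25) lower. None passed over all genes (HYOU1 adjusted p = 0.467).

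In this comparison 0 genes passed (limma, smallest adjusted p = 0.390), with 1454 at an unadjusted p under 0.05. The F test among the 3 groups called 0 genes (limma, smallest adjusted p = 0.652), with 1318 at an unadjusted p under 0.05. With the first principal component as covariate 68 genes passed for the mean of both mutants, 31 higher and 37 lower, and 2 in the F test. These 68 included ATP2A2 (0.27, adjusted p = 0.0333) and the ER co-chaperone DNAJB11 (0.39, adjusted p = 0.0421), named after their values were seen. Whichever array was left out, that setting called 0 genes.

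The effects of Del52 and Ins5 correlated across genes at 0.580, with 69.7% of genes on the same side of 0. Genes are not independent replicates, and both effects share the wild-type arrays. Simulated groups without any effect against those arrays gave a mean correlation of 0.456, with 95% of draws between -0.680 and 0.945. Simulated without the main axis, the mean was 0.50 (0.473 to 0.531), and the observed correlation lay above that range, as did that with the first principal component as covariate (0.580). The observed arrays hold the axis, which that simulation leaves out, so its narrow range cannot judge the correlation found without the covariate. The covariance was 0.00728, against 0.0134 in the simulation with the axis and 0.0130 (0.0118 to 0.0142) without it. It was therefore not above the value that shared controls give alone. With the first principal component as covariate the covariance was 0.00721. Both covariances lay below the range simulated without the axis, so that simulation does not describe these arrays. Its range therefore cannot judge the correlation found with the covariate either. The 3 wild-type arrays were too few to split. With the first principal component as covariate, HDC was the 1 gene shared by the lists of 4 and 7. Both comparisons use the same wild-type arrays and covariate, and none of these calls was made with any 1 array left out.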

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

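Splits of the arrays, the comparison of probe sets and the test for 2 cell populations were planned before their values were seen, whereas the remaining tests here were chosen only after the results were seen. Between Del52 and Ins5, 6 lists stood out because the direct test of the difference between the mutants passed its threshold. The camera adjusted p was 1.4e-06 for the PERK-ATF4 list, 0.00158 for cytosolic heat shock, 0.00358 for ribosome biogenesis and MYC targets, 0.00841 for cholesterol biosynthesis, 0.0164 for the proteasome and 0.0375 for JAK-STAT targets. Each of these 6 lists had an adjusted p = 0.637 with an estimated correlation. The 10 splits of these 6 arrays are too few to judge chance: 2 called as many lists as the real 6, and the highest other count was 8. No formal outlier test was run. Del52 replicate 1 was tested as an explanation for the PERK-ATF4 list only. Without that array, 1 of the 6 lists was still called by camera (adjusted p = 0.0492).

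PERK-ATF4 genes were lower in Del52 than in wild type and in Ins5. The main axis of the arrays is argued against as the whole cause, since with it as covariate the medians were -0.21 against wild type and -0.32 against Ins5. Del52 replicate 1, which stood apart on the second component (-0.79) and had the highest labelling spike (6.59), may carry much of the difference: without it the medians were -0.061 and -0.17, and the second value does not decide. Shared variation of these genes between arrays of a group also stays open (adjusted p = 0.809 and 0.637 with an estimated correlation), as does an effect of Del52 itself. A technical difference stays open as well. The hybridisation spike was higher in every Del52 array (at least 6.07) than in any other array (at most 6.04), whereas the labelling spike did not separate Del52. A difference in hybridisation cannot be told apart from an effect of Del52. Only 10 splits exist for each comparison, too few to judge chance: 5 and 2 of them gave a median as large in size as the real 0.23 and 0.33, and the highest others were 0.52 and 0.54.

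The first principal component held most of the variance, and no group of the design runs along it, so no biological explanation from the design was tested. Within both mutants replicate 2 lay lowest on it (-0.30 in Del52, -0.27 in Ins5) and replicate 3 highest (0.27 and 0.30). Wild-type replicates 2 and 3 lay the other way (0.57 and -0.57). A cause shared by sets of arrays from different groups was not tested. Noise of single probe sets is argued against, because the slopes of different probe sets of 1 gene correlated at 0.753 (95% interval 0.703 to 0.798, 535 genes). A mixture of 2 populations is argued against by shares that differed by -0.188 on the linear scale and by 0.0305 on the log2 scale. For cells of other types, lymphoid genes correlated with the axis (Pearson r = 0.853, exact adjusted p = 0.0121, n = 9 arrays). Granulocyte and monocyte genes (r = -0.847, exact adjusted p = 0.0121) and fibroblast and epithelial genes (r = -0.562, exact adjusted p = 0.166) ran opposite. Of random gene sets of the same size and level, 23.7%, 23.1% and 63.5% correlated as closely. The rule for this test counted opposite directions against such cells, and a condition on marker levels was added to it. Only 0 of 22, 1 of 30 and 4 of 25 of these genes lay above the highest antigenomic control. Signal within that span can be background, so these correlations neither show nor exclude such cells. Differences in RNA integrity could not be excluded (actin 3-prime minus 5-prime signal, r = -0.742, exact adjusted p = 0.0598, n = 9), nor could labelling or hybridisation yield (spike r = -0.334, exact adjusted p = 0.441, n = 9; 30 relations adjusted together).

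With the first principal component as covariate, 68 genes passed for the mean of both mutants, against at most 14 in the other 99 of 100 splits. Only 1 of 100 splits, the real one, was as large. The covariate was computed from these arrays and chosen after the data were seen, and splits uneven on it lose precision. The splits were not matched for this, so chance was not excluded for this count. In the F test, 5 of 100 splits called as many as the real 2 (highest other 6), so chance was not excluded. For the pairs of groups the 10 splits are too few: 2 of them called as many as the real 4 in Del52 against wild type (highest other 22), 1 as many as 7 in Ins5 against wild type (highest other 1), and 10 as many as 0 between the mutants (highest other 5). Leaving out any 1 array left 0 genes in each of these comparisons, so the calls may rest on the full set of arrays as much as on the mutants. Each of those fits also had fewer arrays and less power, which was not separated from dependence on single arrays.

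Without a covariate, 0 genes passed (limma; unadjusted p under 0.05 in 1285, 1351, 1052, 1454 and 1318 genes), so every split was as large: 10 of 10 for Del52 against wild type (highest other 545), 10 of 10 for Ins5 against wild type (highest other 0), 10 of 10 for Del52 against Ins5 (highest other 0), 100 of 100 for the mean of both mutants (highest other 498) and 100 of 100 for the F test (highest other 2). How the splits that called 545 and 498 genes lie relative to the main axis was not tested. For lists, 9 of 10 splits called as many as the real 2 in Del52 against wild type (highest other 5) and 10 of 10 as many as the real 0 in Ins5 against wild type (highest other 6). For the mean of both mutants 61 of 100 splits called as many as the real 2 (highest other 10), so chance was not excluded.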

How the results depend on the processing

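The first principal component as covariate and the fit without both arrays at its ends were chosen only after the results were seen. Gene counts stayed at 0 (limma) in Del52 against wild type, Ins5 against wild type, Del52 against Ins5, the mean of both mutants and the F test, with 3 exceptions. Array weights gave 3190, 4017, 0, 6232 and 5345 genes, with a weight of 67.0 on wild-type replicate 1, against 0.237 to 1.82 elsewhere. Variances without moderation gave 2, 9, 1, 8 and 6. The covariate gave 4, 7, 0, 68 and 2, and a range of 0 to 0 with each array left out. With it, camera called 7, 1, 9 and 5 lists in the first 4 comparisons, instead of 2, 0, 6 and 2, and 0 with an estimated correlation. For the PERK-ATF4 list, adjusted p-values with an estimated correlation, by fry, and with covariate and estimated correlation were 0.809, 0.848 and 0.699 in Del52 against wild type. They were 0.637, 0.664 and 0.673 in Del52 against Ins5, and 1.00, 0.829 and 0.954 for the mean of both mutants. ER chaperones passed between the mutants with genes above the median level (0.0314), the mean of all probe sets (0.0102) and without both end arrays (0.0336), and antioxidant enzymes passed for the mean of both mutants with genes above the median level (0.0418). With each array left out, the PERK-ATF4 adjusted p ranged from 1.7e-13 to 0.0384 (Del52 against wild type), 2.7e-12 to 0.0825 (Del52 against Ins5, highest without Del52 replicate 1), 2.0e-07 to 0.347 (mean of both mutants, highest without wild-type replicate 3) and 0.0270 to 0.911 (Ins5 against wild type, lowest without wild-type replicate 2). For ER chaperones between the mutants it ranged from 0.00986 without Del52 replicate 3 to 0.674 without Del52 replicate 1. It also passed there without Ins5 replicate 2 and without each wild-type array. Between the mutants, JAK-STAT was lost with the mean of all probe sets (0.230), and the proteasome call for the mean of both mutants was lost without both end arrays (0.226). The correlation of the mutant effects ranged from 0.401 to 0.841 with each array left out. For the 10 list calls, 127 of 180 values under other settings were past the threshold and 53 were not. For the 86 list results without a call, 77 of 1548 values were past it. No named gene was called to begin with, and 60 of 1811 values were past it, 54 of them with array weights. By the direction of the test no called result reversed, but the PERK-ATF4 median for the mean of both mutants turned positive without Del52 replicate 1 (0.0064) and without wild-type replicate 3 (0.014). Among results that were not called, the sign changed in 38 values for stress lists, 161 for other lists and 14 for named genes. The cause was not tested. Many named genes lay within the span of the antigenomic controls, so absence of change is not shown for them.

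With the replicate block, gene counts were 0 in each comparison, camera called 2, 0, 9 and 2 lists, and ER chaperones passed between the mutants (0.0426). Deviations of the arrays from their group means were then correlated between groups. Of 9 pairs of arrays with the same number, 2 had deviations correlated above 0.1 (range -0.923 to 0.643), and 0 of 9 arrays matched best with its own number. Replicate 2 of Del52 and of Ins5 matched best with wild-type replicate 3 (0.869 and 0.836), and replicate 3 of both with wild-type replicate 2 (0.785 and 0.876). The block by number therefore did not follow this resemblance.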

Other observations

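All tests described here were chosen only after the main axis was seen. The axis from wild-type replicate 3 to wild-type replicate 2 is itself made of gene expression, so a correlation of a list with it says little. Random sets of genes matched in number and level to the cholesterol list had a median absolute correlation of 0.794 with it. The distance that a list moved along the axis was therefore compared with 1000 such random sets for each of the 24 lists, without adjustment. Genes of a list can vary together for reasons other than the axis, which random sets leave out.

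Cholesterol biosynthesis genes, which carry the sterol pathway, moved further toward wild-type replicate 2 than the random sets did (slope 0.59 log2 per unit of the axis, with 0% of random sets as far). Glycolysis and hypoxia genes (slope 0.37, 0%) and cytosolic heat shock genes (0.35, 0%) moved the same way, as did MAPK output (0.30, 0.4%) and ribosome biogenesis and MYC targets (0.25, 0.5%). PERK-ATF4 genes moved the opposite way (slope -0.64, 0%), with erythroid genes (-0.23, 0.8%) and cell cycle genes (-0.20, 1.2%). By correlation with the axis instead of distance, more random sets did as well: 57.9% for PERK-ATF4 genes, 60.6% for MAPK output, 53.2% for erythroid genes, 33.5% for ribosome biogenesis, 26.6% for heat shock, 21.3% for the cell cycle, 6.5% for cholesterol and 3.8% for glycolysis and hypoxia. The large slopes of the first 3 can therefore come with spread off the axis, and their correlations over 9 arrays did not pass (Pearson r = -0.690, 0.646 and -0.713, exact adjusted p = 0.0757, 0.105 and 0.0695; Spearman rho = -0.683, 0.583 and -0.633; r = -0.574, 0.365 and -0.422 without wild-type replicates 2 and 3; 30 relations). By distance, for the interferon response the share was 5.9%, for antioxidant enzymes 14.8%, for ER-associated degradation 33% and for ER chaperones 80.9%.

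Between the arrays at the ends of the axis, 484 genes were higher and 610 lower by a log2 difference of at least 1 in wild-type replicate 2. This compares 1 array with 1 array and has no test. The chemokine CXCL8 read 7.63 against 3.83, the interferon-induced membrane protein BST2 9.45 against 6.52, and the collagen COL15A1 9.35 against 4.81. The stress factors ATF3 and JUN read 5.74 against 8.96 and 5.41 against 8.68, the proteoglycan SRGN 1.72 against 6.73, and CTH, an enzyme of cysteine synthesis, 5.43 against 9.27.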
